A study of Emberiza melanocephala with 4 samples.

How the data were processed

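RNA-seq labelled as testis of wild-caught black-headed buntings was available as 4 libraries, 1 per testicular state named in the labels (sensitive, early stimulated, late stimulated and refractory). Per the labels' protocols, tissue was powdered in liquid nitrogen, total RNA was extracted with Tri reagent and libraries followed Illumina's usual protocol. Trimmomatic is named in the submitters' processing notes. The aligner is not given in the sources used here. Transcripts were assembled separately in each library with StringTie 1.3.3b, guided by the Ensembl 89 annotation of the collared flycatcher (Ficedula albicollis, assembly FicAlb_1.4), a different songbird species, per the file headers. The assembly was not limited to annotated transcripts, so each file also lists transcripts that match no reference gene. The header of the library labelled sensitive uses another abbreviation in its command line than its title does.

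The deposited values are FPKM, TPM and mean per-base coverage for each transcript, and coverage for each exon, as StringTie wrote them per the file headers. None of them is a read count, and no scaling between libraries was recorded. Coverage divided by FPKM was constant within a file and gave the total aligned bases, from 120.5 Mb in the library labelled sensitive to 428.4 Mb in late stimulated. The lowest coverage of a transcript without a reference match was 2.5 in each file, which sets a listing floor of 20.8, 12.5, 5.84 and 7.86 FPKM in the order of the states. Reference-matched transcripts are listed below that floor too. Such a file gives no count-based interval or limit, and an unlisted gene has no measured 0.

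Gene values were made in 2 ways. The first, fixed before the data were examined, summed the FPKM of all transcripts carrying a gene's name, or its reference ID where it had no symbol, and took 0 where none was listed. A large part of the genes then appeared or disappeared with the match of an assembled transcript to the annotation, as for ACTB, which had no transcript under its name in the library labelled sensitive although its exons were covered at 1265 FPKM. The second value, chosen after the data were examined, is the coverage of the gene's exons by all listed transcripts on its strand or without a strand, divided by exon length and by the library's aligned bases, in FPKM units. The exons were those of the gene's reference-matched transcripts in any of the 4 files. Where a gene was listed under its name, the values agreed within 0.1 on the log2 scale in 88.0% of 5594 cases. Overlapping genes and paralogs can share this coverage, and genes with no match in any file have no value of either kind.

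In 5 comparisons, genes were counted as higher or lower at a difference of at least 1 in log2(FPKM + 1), that is 2-fold on values plus a pseudocount of 1, among genes at 1 FPKM or more in at least 1 of the 2 libraries. Differences on this scale understate the change of low genes. There were no tests and no p-values, since each state has 1 library. For a gene list, the median difference was set beside those of 10000 random lists of the same size, drawn from 20 bins of mean level, for lists with at least 3 measured members. Such percentiles describe these libraries. List medians fixed for values under the genes' names are given on exon coverage, and under the names too where that moved a list across percentile 2.5 or 97.5.

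Genes named in the text were to be the 8 highest and 8 lowest of each comparison at 5 FPKM or more, up to 4 members of each list described, and 28 key genes. Because this rule picked many genes through their listing alone, the same rule was applied to exon coverage after the data were examined, and most genes named come from it or from the lists. Others named, such as members given for contrast and further list members, were chosen after their values were seen. Of 27 lists, 22 were fixed before the data were examined, with ribosomal proteins defined by their symbols, which also take in RPS27L and RPL22L1. The remaining 5, for photoreceptors and the visual cycle, neurons and synapses, hypothalamic peptides and the pineal gland, trunk and gonadal mesoderm regulators, and secreted liver proteins, were written from textbook markers afterwards. Single-gene values of some list members are not reported here and are left out of the figure of list genes, while list counts and medians keep all members.

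The code for gene values was checked on simulated data made from the library labelled late stimulated, with 200 genes changed by known folds and reference names removed from 50% of named transcripts. When all transcripts over a gene were changed, exon coverage recovered the change within 0.1 on the log2 scale for 100% of the genes at each of the folds 0.25, 0.5, 2 and 4 among 1581 genes, and values under the genes' names for 66%, 40%, 48% and 56%. Since exon coverage does not use names, it must return the change there, so this shows that the code runs as meant and does not support the choice of value. The genes changed in that simulation shared no transcript with another gene, so it does not cover overlapping genes. It replaced an earlier one without that limit, in which only named transcripts were changed and the pseudocount was left out of the true value. There exon coverage recovered 52%, 94%, 92% and 86%, and 78%, 94%, 94% and 86% once the pseudocount was put back. The rest of the shortfall was not divided between the other choices. In a simulated late against early stimulated comparison of 1347 genes, a list of 20 genes raised by 1 reached percentile 100, and 8% of 200 random lists fell outside the central 95%, slightly more than the nominal share. Scripts used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

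Alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter on low values, a minimum of 5 FPKM, only genes listed in all 4 files, median-of-ratios and upper-quartile scaling, rescaling to TPM after leaving out the 20 highest genes, the highest transcript of each gene, and a difference of at least 2. Added after the data were examined were exon coverage, exon coverage of genes covered in both libraries, on any strand, with median-of-ratios scaling, with uncovered genes set to the floor, and the same without genes covered in neither library. Median-of-ratios factors on exon coverage shift all differences by 0.15, 0.12, 0.26, -0.19 and 0.07 in the order in which the comparisons are reported.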

Results

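The black-headed bunting (Emberiza melanocephala) is a migratory songbird that breeds seasonally. RNA labelled as testis, from birds caught from the wild, was sequenced in 4 libraries. There was 1 for each testicular state that the labels name: sensitive, early stimulated, late stimulated and refractory. In photoperiodic birds, the sensitive state is usually taken as the one in which long days can still start gonadal growth, and the refractory state as the one in which long days no longer maintain it. The comparisons below follow the order of these states. With 1 library per state there is no replicate check, so differences describe these libraries and carry no p-value. Photoreceptor genes, which are known from the retina, were abundant in 3 of the libraries, and each library is therefore called by its label.

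The aligned bases behind the deposited values came to 120.5 Mb in the library labelled sensitive, 200.8 Mb in early stimulated, 428.4 Mb in late stimulated and 318.1 Mb in refractory. The files listed 10406, 15542, 20488 and 18303 assembled transcripts in the same order. Transcripts matching a reference gene named 2239 genes over the 4 files, 1509 of them with a gene symbol. A transcript without a reference match was listed only from a coverage of 2.5, which equals 20.8 FPKM in the library labelled sensitive, 12.5 in early stimulated, 5.84 in late stimulated and 7.86 in refractory. A gene listed at 0 may therefore be present under these floors, and where its level in the other library is lower than the floor too, no direction is measurable. Levels below are the coverage of a gene's exons by all listed transcripts, in FPKM units, unless the text says "under the gene's name". This exon coverage was chosen after the data were examined, because 382, 395, 277 and 337 genes in the 4 libraries were absent under their own name while other listed transcripts covered their exons.

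Of 28 genes of steroid synthesis, hormone reception, Sertoli cells and germ cells fixed before the data were examined, 2 carried a name in these files. INHA, the inhibin alpha subunit, was at 3.81 FPKM in the library labelled sensitive and was listed at 0 in the other libraries, where that level lies under the floor. INHBA, the shared inhibin and activin beta subunit, was listed at 0 in sensitive and reached 6.50 FPKM in early stimulated, 4.62 in late stimulated and 2.89 in refractory, all under the floor of the sensitive library. Germ-cell lists fixed in advance held 165 genes, of which 4 were named. Among these, TDRD6, a component of germ-cell granules, was at 1.82 FPKM in sensitive and at 0 in the others. GFRA1, the receptor subunit of spermatogonial stem cells, was at 7.60, 1.92, 0.90 and 2.65 FPKM in sensitive, early stimulated, late stimulated and refractory. MEIG1, needed for building sperm, was at 3.45, 2.63, 4.69 and 5.74 FPKM, and UCHL1, found in both spermatogonia and neurons, at 14.4, 206, 365 and 171 FPKM. A missing name does not show that a gene was silent, since most assembled transcripts matched no reference gene.

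The first comparison asks how the library labelled early stimulated differed from the library labelled sensitive. Photoreceptor genes were abundant in early stimulated and almost without coverage in sensitive. PDC, the phosducin that binds transducin subunits, reached 200 FPKM, the cone phosphodiesterase subunit PDE6H 189 FPKM, the guanylate cyclase activators GUCA1C and GUCA1A 136 and 112 FPKM, and cone transducin GNAT2 101 FPKM, and each was listed at 0 in sensitive. All 13 measured members of the photoreceptor and visual cycle list were higher by at least 1 on the log2(FPKM + 1) scale, with a median difference of 5.94, which was at percentile 99.99 of 10000 random lists matched on level. With the 11 members at 0 in sensitive set to that library's floor, the median was 2.22. PDE6G at 30.8, KCNV2 at 30.5, RBP3 at 26.7, NXNL2 at 26.6 and RLBP1 at 24.7 FPKM lay less than 2-fold over that floor. A difference of 1 is not measurable for them. This list and the lists of neuron, trunk and liver genes were written from textbook markers after these genes had been noticed.

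Neuronal genes were higher as well. The neuron and synapse list had 27 of 28 measured members higher, 2 of them under the sensitive floor, and none lower, with a median of 5.75, or 2.18 with uncovered members at the floor. Others, such as GAP43 at 21.6, GLRB at 23.8, SNCB at 36.6 and NCS1 at 37.8 FPKM, lay less than 2-fold over that floor. The calcium-binding protein CALB2 reached 344 FPKM, the endophilin SH3GL2 261 FPKM, the GABA-synthesising enzymes GAD1 and GAD2 169 and 110 FPKM, the nicotinic receptor subunit CHRNB3 151 FPKM and the RNA-binding protein ELAVL4 127 FPKM, all from 0 in sensitive. The secretogranin SCG3 stood at 272 against 4.21 FPKM, and the neuronal enolase ENO2 at 140 against 1.84 FPKM. The genes with the largest differences included ACBD7 at 617 FPKM, RD3L at 381, TAGLN3 at 327 and SPOCK3 at 199, each listed at 0 in sensitive. The calcium buffer CALB1, on the list of adrenal and kidney genes fixed in advance, was at 105 FPKM against 0, and it is also a member of the neuron list. THRB, a thyroid hormone receptor, was at 25.5 FPKM against 0, close over the sensitive floor of 20.8 FPKM.

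Genes higher in the library labelled sensitive included FABP4, a fatty-acid carrier of fat and endothelial cells (ENSFALG00000008633, 4 exons on the minus strand of FicAlb_1.4 scaffold JH603220.1 from 5106276 to 5110105), at 538 FPKM, and AHSG, the secreted plasma protein fetuin-A, at 527 FPKM, both listed at 0 in early stimulated. KCNMB1, a smooth-muscle potassium channel subunit, was at 195 FPKM, SLC29A1, a nucleoside transporter, at 54.7 FPKM, and NPC2, a lysosomal cholesterol carrier, at 54.4 FPKM, again from 0. The protease inhibitor SERPINE2 was at 378 against 8.88 FPKM, and SOD3, the extracellular superoxide dismutase, at 139 against 3.42 FPKM. All 9 measured transcription factors of the trunk and gonadal mesoderm list were lower in early stimulated, 2 of them under its floor. The list had a median of -4.30, or -1.68 with uncovered members at the floor. NR2F2 stood at 308 against 46.2 FPKM and LHX9, which acts in the early gonad, at 37.4 FPKM in sensitive, with a difference of -1.68 that reversed to 3.90 under its name, where LHX9 had no transcript in sensitive. SNAI2 at 109 FPKM, HAND2 at 51.8, OSR1 at 42.8 and HOXA7 at 25.8 in sensitive were listed at 0 in early stimulated. TCF21 at 9.65 and HOXD8 at 7.06 FPKM lay under the floor of the early stimulated library, so their absence there is not measurable. The mitochondrial cholesterol-binding protein TSPO was at 28.3 against 0 FPKM. The secreted collectin COLEC10 was at 54.2 against 0 FPKM, and it and AHSG were lower among the 3 named genes of the liver list, while the last lay under the floor.

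**Figure D1:**
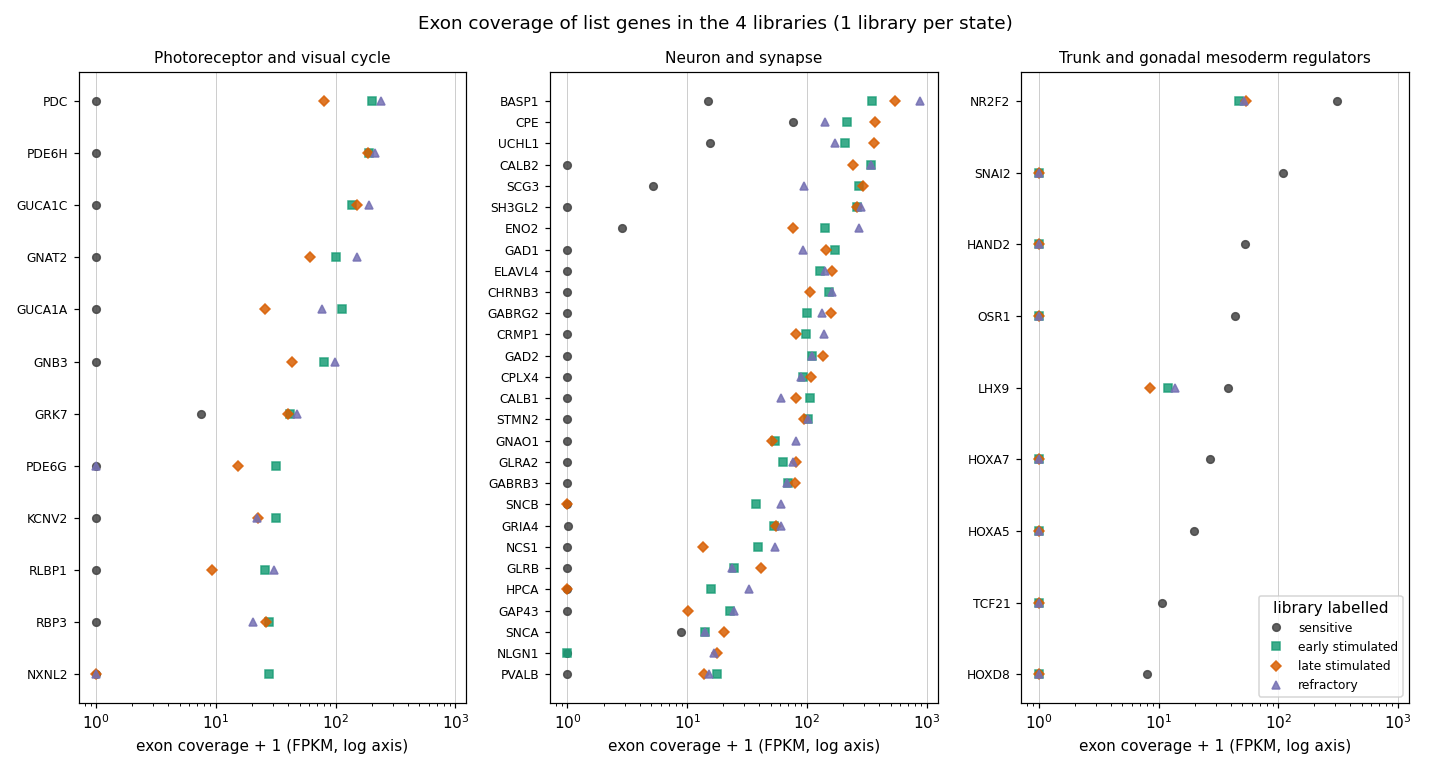
Exon coverage plus 1 in FPKM on a log axis for genes of 3 lists, with 1 point per library and marker shape and colour giving the library's label. Points at the left edge are genes listed at 0. Photoreceptor and neuron genes sit near the left edge in the library labelled sensitive, as for PDC at 0 against 200 FPKM in early stimulated, and the trunk and gonadal regulators show the opposite, as for HAND2 at 51.8 FPKM in sensitive and 0 elsewhere.

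Ribosomal-protein genes were lower in the library labelled early stimulated in 28 of 29 measured members, 1 of them under the floor, with a median of -2.17, under all 10000 random lists. RPL37 stood at 337 against 1622 FPKM, RPL30 at 54.6 against 459 and RPS20 at 106 against 524. Under the genes' own names the median was -2.42. The shortest of 5 equal groups of 1071 genes had a median of -0.30. Of the 9 measured genes encoded in mitochondrial DNA, 6 were lower and 1 higher, with a median of -1.34 at percentile 1.06, and at percentile 6.88 under the genes' names. COX1 was at 1.22 FPKM against 146 in sensitive, and COX3 went the other way, at 126 FPKM against 1.59 in sensitive. Mitochondrial transcripts held only 4382 of 961753 TPM in sensitive and 2003 of 956880 in early stimulated, so these values rest on little signal. All 4 named clock genes were higher, with a median of 3.77 at percentile 99.03, or 1.13 with uncovered members at the floor. Under the genes' names the percentile was 95.4. NFIL3 stood at 279 against 39.7 FPKM and NR1D2 at 63.1 against 21.6 FPKM, while HLF at 35.9 and TEF at 25.9 FPKM were listed at 0 in sensitive. Both HLF and TEF lay less than 2-fold over the sensitive floor of 20.8 FPKM, so a difference of 1 is not measurable for them. Antioxidant and heat-shock genes had 3 of 7 lower and none higher, with a median of -0.84 at percentile 12.3, or -0.01 with the uncovered member at the floor. Housekeeping genes moved apart: ACTB stood at 1265 in sensitive against 296 FPKM, GAPDH at 110 against 739 and GPI at 87.4 against 813, and the median of 9 members was -0.43. Under their names ACTB and GAPDH reversed, to 8.22 and -6.79, since ACTB had no transcript under its name in sensitive and GAPDH none in early stimulated.

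Counted as fixed in advance, with a gene's transcripts under its own name and 0 where it had none, 589 genes were higher and 459 lower in early stimulated by at least 1 on the log2 scale, of 1474 genes at 1 FPKM or more in either library. On exon coverage 614 were higher and 444 lower of 1782, and among 1203 genes covered in both libraries 218 were higher and 261 lower. With genes uncovered in 1 of the libraries at its floor, and those covered in neither left out, the balance turned, to 359 higher and 487 lower, so a majority of higher genes is not firm. This setting counts as lower a gene at 0 in sensitive and far under the sensitive floor in early stimulated. A majority of lower genes is therefore not firm either. Of the 1048 calls under the genes' names, 854 were kept on exon coverage and 22 had the opposite sign. The naming rule fixed in advance picked 16 genes on values under the genes' names, and 4 of them (DDX5, NAP1L1, HMGB1 and SRSF5) differed by less than 1 on exon coverage.

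The next comparison follows stimulation from the library labelled early stimulated to the library labelled late stimulated. These libraries were close to each other. On exon coverage 174 genes were higher and 188 lower of 1682, which median-of-ratios scaling turned to 190 and 166, and among 1506 genes covered in both, 58 were higher and 128 lower. The counts under the genes' own names, as fixed in advance, were 386 higher and 308 lower of 1515. Of those 694 calls, 306 were kept on exon coverage, and 522 had no transcript under the gene's name in one of the libraries. All 16 genes picked by the rule fixed in advance, among them GNB1, OGT, ACTB and ENO1, differed by less than 1 on exon coverage.

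Photoreceptor genes were lower in the library labelled late stimulated, with 6 of 13 measured members lower by at least 1, none higher and a median of -0.88, under all random lists. PDC stood at 79.0 against 200 FPKM, GUCA1A at 24.9 against 112 and RLBP1, a retinoid carrier of the visual cycle, at 8.32 against 24.7 (reversed to 3.22 under its name, which no transcript carried in early stimulated), while NXNL2, a photoreceptor survival factor, went from 26.6 FPKM to 0. Members within the threshold included PDE6H at 184 against 189 FPKM, GUCA1C at 149 against 136, GNAT2 at 59.8 against 101 and GNB3 at 42.1 against 78.5. Neuronal genes mostly stayed within the threshold, with 2 of 29 higher, 4 lower and a median of 0.04 at percentile 86.5. Under the genes' names the median was 0.28 at percentile 99.4. Within that list UCHL1 was at 365 against 206 FPKM, a difference of less than 1. The synuclein SNCB at 36.6 FPKM and the calcium sensor HPCA at 14.7 FPKM in early stimulated were listed at 0 in late stimulated, and NLGN1, a synaptic adhesion protein, was at 16.7 FPKM in late stimulated and at 0 in early stimulated.

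Ribosomal-protein genes were again lower, in 9 of 27 measured members with 1 higher, and their median of -0.89 lay under all random lists. RPS21 was at 35.7 against 138 FPKM and RPL37 at 147 against 337. RPL35, the member that was higher, was at 10.5 FPKM from 0, a level under the early stimulated floor. The mitochondrial-encoded genes had a median of -0.78 at percentile 0.91, or 2.75 under the genes' names, with COX3 at 0.11 against 126 FPKM and COX1 the other way at 21.8 against 1.22. Of the 4 clock genes 0 passed the threshold, and their median was 0.01. Housekeeping genes had a median of -0.59 at percentile 0.72, against percentile 36.2 under the genes' names, with 1 of 9 lower by at least 1, and antioxidant and heat-shock genes a median of -0.49 at percentile 2.98. The sign of the housekeeping median turned, to 0.087, with only the 4 members listed under their names in every library. Beyond these lists, CMC1, a mitochondrial assembly factor, at 46.1 FPKM and UGDH, which makes UDP-glucuronate, at 21.8 FPKM were listed at 0 in early stimulated. Short genes leaned lower in late stimulated. Across 1292 genes, which are not independent replicates, the difference had a Spearman correlation of 0.25 with exon length, and its median was -0.31 in the shortest of 5 equal groups of genes.

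The library labelled late stimulated was also set against the library labelled sensitive. The same groups parted as for early stimulated. All 12 measured photoreceptor genes were higher, 2 of them under the sensitive floor, with a median of 4.78, or 1.24 with uncovered members at the floor. Among the other 10, KCNV2 at 21.5, GUCA1A at 24.9, RBP3 at 25.4 and GNB3 at 42.1 FPKM lay close over that floor of 20.8 FPKM. A difference of 1 is not measurable for them. All 27 measured neuron genes were higher, 4 of them under that floor, with a median of 6.32, or 2.27 at the floor. GLRB at 40.7 FPKM lay less than 1 over it on the log2(FPKM + 1) scale. RD3L reached 466 FPKM, TAGLN3 362, ACBD7 316, SH3GL2 261, CALB2 241, LAPTM4B 206 and PDE6H 184, each from 0 in sensitive. All 9 trunk and gonadal regulators were lower, with a median of -4.30, or -2.16 at the floor. TCF21 at 9.65 and HOXD8 at 7.06 FPKM in sensitive lay less than 2-fold over the late stimulated floor of 5.84 FPKM. FABP4, AHSG, KCNMB1 and SNAI2 were at 538, 527, 195 and 109 FPKM in sensitive and listed at 0 in late stimulated, as were the tropomyosin TPM4 at 79.2 FPKM and GSTZ1 at 65.0. Ribosomal-protein genes were lower in 29 of 30 members and higher in 1 that lay under the floor, with a median of -2.81, RPS20 standing at 73.1 against 524 FPKM and RPS21 at 35.7 against 506. Short genes as a whole leaned the same way, with a median of -0.80 in the shortest of 5 equal groups of 1101 genes and a Spearman correlation of 0.19 with exon length. Of the 9 mitochondrial-encoded genes 7 were lower, with a median of -1.72 at percentile 0.17. All 4 clock genes were higher, with a median of 3.66 at percentile 99.04, or 1.34 at the floor. TEF at 20.4 FPKM lay under the sensitive floor, and HLF at 33.8 FPKM lay less than 2-fold over it. A difference of 1 is not measurable for HLF, nor a direction for TEF. Housekeeping genes had a median of -1.02 at percentile 7.79, and antioxidant and heat-shock genes one of -1.10 at percentile 9.84. Under the genes' names 672 genes were higher and 491 lower of 1563. On exon coverage these were 602 and 501 of 1770, and among 1253 genes covered in both libraries 217 and 369. With uncovered genes at the floor, and those covered in neither library left out, they were 291 and 612, which turns the balance. Genes at 0 in sensitive and far under its floor in late stimulated count as lower there, so neither majority is firm.

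The step into the refractory state was examined by setting the library labelled refractory against the library labelled late stimulated. Photoreceptor genes were higher in refractory in 6 of 12 measured members and lower in 1, with a median of 0.74 at percentile 98.2. Under the genes' names the median was 0.34 at percentile 67.8. PDC stood at 237 against 79.0 FPKM, GUCA1A at 76.1 against 24.9, GNB3, the cone transducin beta subunit, at 98.4 against 42.1 and GNAT2 at 150 against 59.8. PDE6G, the rod phosphodiesterase subunit, was at 14.4 FPKM in late stimulated and listed at 0 in refractory. Ribosomal-protein genes were higher in 17 of 29 members, 2 of them under the floor, and lower in 2, with a median of 1.27, above all random lists. RPS21 was at 181 against 35.7 FPKM, RPS15A at 241 against 56.0 and RPL37 at 536 against 147, whereas RPL27A was at 13.8 FPKM in late stimulated and at 0 in refractory.

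Neuronal genes split, with 5 of 29 higher, 3 lower and a median of -0.01 at percentile 9.60. Under the genes' names the median was -0.25 at percentile 1.89. ENO2 was at 269 against 75.4 FPKM, and SNCB at 59.6 and HPCA at 31.6 FPKM were listed at 0 in late stimulated. SCG3 was at 92.9 against 294 FPKM, the prohormone-processing enzyme CPE at 141 against 371 and UCHL1 at 171 against 365. The direction reversed under the genes' names for ENO2 at -6.24, SCG3 at 5.13 and UCHL1 at 7.42, each without a transcript under its name in 1 of the libraries. The thyroid hormone receptor THRB was at 14.8 against 30.8 FPKM. Clock genes had 0 of 4 past the threshold and a median of -0.45 at percentile 3.17, with NFIL3 at 195 against 302 FPKM and HLF at 21.4 against 33.8. Housekeeping genes had 4 of 9 higher and none lower, with a median of 0.77 at percentile 98.0, against percentile 41.6 under the genes' names, GAPDH standing at 918 against 367 FPKM and ACTB at 410 against 193. Their median turned to -0.069 with only the 4 members listed under their names in every library. Antioxidant and heat-shock genes had 3 of 7 higher, 1 of them under the floor, and a median of 0.04, and mitochondrial-encoded genes 2 of 7 higher, 2 lower with 1 of these under the floor, and a median of 0.26. Other large differences were COX17, a copper chaperone, at 37.8 FPKM from 0, and LSM7 at 35.1 and CTNNBIP1 at 25.1 FPKM in late stimulated, both listed at 0 in refractory. Among loci of named or unnamed transcripts at 62.3 FPKM or more in late stimulated, 151 of 2603 (5.80%) were at 0 in refractory. The reverse held for 56 of 2430 (2.30%). Whether such a 0 is a low level or a transcript that was not assembled was not tested.

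On exon coverage 318 genes were higher and 181 lower in refractory of 1714, which makes 63.7% of the calls higher. Median-of-ratios scaling gave 261 and 227, or 53.5%, since it moves this comparison by -0.19 for every gene. Among 1541 genes covered in both libraries 228 were higher and 98 lower, and under the genes' names 460 were higher and 393 lower of 1613. Some scalings turned that last majority, to 407 and 431 with median-of-ratios and 404 and 437 with upper-quartile factors, while TPM without the 20 highest genes kept it at 449 and 404. Of the 853 unscaled calls under the names 437 were kept on exon coverage, and 12 of the 16 genes picked by the rule fixed in advance differed by less than 1. As before, the difference followed gene length, with a Spearman correlation of -0.26 across 1313 genes and a median of 0.49 in the shortest of 5 equal groups.

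The last comparison set the library labelled refractory against the library labelled sensitive. Photoreceptor and neuron genes were higher here too, over the sensitive floor in 10 of 11 and 25 of 29 measured members, with 1 and 2 more under it. The medians were 6.27 and 6.09, or 2.66 and 2.08 with uncovered members at the floor. KCNV2 at 21.2, RLBP1 at 29.6, GLRB at 22.8, GAP43 at 23.5 and HPCA at 31.6 FPKM lay less than 2-fold over that floor. A difference of 1 is not measurable for them. ACBD7 reached 797 FPKM, RD3L 503, TAGLN3 387, CALB2 341, SH3GL2 283, the retinal G-protein subunit GNG13 274 and PDC 237, each from 0. ENO2 stood at 269 FPKM against 1.84 and BASP1, a protein of growing axons, at 880 against 13.9. All 9 trunk and gonadal regulators were lower, 1 of them under the refractory floor, with a median of -4.30, or -1.60 at the floor. TCF21 at 9.65 FPKM in sensitive lay less than 2-fold over that floor. FABP4, AHSG, KCNMB1 and SNAI2 were again listed at 0. SERPINE2 was at 7.56 against 378 FPKM. Ribosomal-protein genes were lower in 22 of 29 members and higher in none, with a median of -1.64, RPL34 standing at 158 against 935 FPKM. The shortest of 5 equal groups of 1102 genes had a median of -0.53. Mitochondrial-encoded genes were lower in 6 of 9, with a median of -1.17 at percentile 1.18, and at percentile 6.03 under the genes' names. Clock genes were higher in 4 of 4, with a median of 3.37 at percentile 98.4, or 1.18 at the floor, and at percentile 96.4 under the genes' names. HLF at 21.4 and TEF at 32.7 FPKM lay less than 2-fold over the sensitive floor, so a difference of 1 is not measurable for them. Housekeeping genes had a median of -0.31, and antioxidant and heat-shock genes one of -0.58. Under the genes' names 686 genes were higher and 461 lower of 1561. On exon coverage 660 and 441 of 1806 genes were higher and lower, and among 1251 genes covered in both libraries 249 and 297. With uncovered genes at the floor, and those covered in neither library left out, they were 366 and 546, which turns the balance. Genes at 0 in sensitive and far under its floor in refractory count as lower there, so neither majority is firm.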

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

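The tests of explanations in this part, the shares of unmatched transcripts, the values on exon coverage and the photoreceptor and neuron lists were chosen after the result was seen. Most of the deposited signal lay outside the named genes: transcripts without a reference gene held 90.7% of TPM in the library labelled sensitive, 92.5% in early stimulated, 93.2% in late stimulated and 91.8% in refractory. No control library sets a level for these shares.

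The pattern that most calls for a second look is the presence of photoreceptor and neuron genes in the libraries labelled early stimulated, late stimulated and refractory and their lack of coverage in sensitive. The higher floor of the shallow sensitive library is argued against only for part of the 33 list genes without coverage there. Of these, 20 had a mean level over 3 times that floor in the other 3 libraries, and 27 lay over it. The median was 3.52 times the floor, with quartiles of 1.18 and 6.25. Both lists were written after such genes had been noticed, so these values speak to their members alone. For a small admixture of neural tissue, 23.9% of 2540 loci abundant in sensitive lay under 25% of that level in all of the other 3 libraries. The median locus kept 59.6% of it in the highest of them. These loci were chosen for being high in sensitive, and no control sets a level for the share. The values speak only to an otherwise unchanged sample. They cannot decide on an admixture into a testis that changed with its state. Libraries or files of a tissue other than the label and the testicular state itself cannot be told apart. For the former, only 3 of 164 germ-cell list genes outside the neuron list were named in any file, too few to tell whether germ-cell genes are missing, and the photoreceptor and neuron lists were written after the pattern was noticed. For the latter, there is 1 library per state. The library labelled sensitive stood apart, with Pearson correlations across loci of 0.62, 0.60 and 0.58 with early stimulated, late stimulated and refractory. Pairs among those libraries reached 0.85 to 0.91. The header of the library labelled sensitive also uses another abbreviation than its title. Neither observation decides between a tissue other than the label and the state.

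The other pattern is that ribosomal-protein and photoreceptor genes were lower in the library labelled late stimulated than in early stimulated and refractory. In late against early stimulated, 9 of 27 ribosomal-protein and 6 of 13 photoreceptor genes were lower by at least 1, and in refractory against late stimulated 17 of 29 and 6 of 12 were higher, 2 of the 17 under the floor. The photoreceptor rise was at percentile 98.2 on exon coverage and at 67.8 under the genes' names. The step may not be confined to these lists, since housekeeping genes had medians of -0.59 and 0.77 on exon coverage, at percentiles 0.72 and 98.0, and -0.18 and 0.08 under the names, at 36.2 and 41.6. This is not firm. With only the 4 housekeeping members listed under their names in every library, the medians changed sign, to 0.087 and -0.069. The list also shares RPLP0 with the ribosomal proteins. Short genes leaned the same way, but after the trend with exon length was removed the medians in late against early stimulated were still -0.71 for ribosomal proteins and -0.55 for photoreceptor genes, at percentiles 0 and 0.07 of length-matched lists, which argues against length as the whole cause. Scaling is argued against as well, since under 3 other scalings the median nearest to 0 of either list was -0.72 in late against early stimulated and 0.54 in refractory against late stimulated. An effect of the state cannot be told apart from a trait of this library with 1 library per state, and it stays open as a hypothesis.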

How the results depend on the processing

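The settings that use exon coverage were chosen after the data were examined. Of 160 alternative counts of genes, 111 stayed within 1.5 times the reported count, including all those with a pseudocount of 0.1, no filter, a minimum of 5 FPKM, other scalings of values under the genes' names, or the highest transcript. The others are given as genes higher and lower. A difference of at least 2 gave 291 lower in early stimulated against sensitive, 175 lower in late against early stimulated, 280 lower in late stimulated against sensitive, 257 higher in refractory against late stimulated and 281 lower in refractory against sensitive, as a stricter rule must give fewer. A pseudocount of 5 gave 188 lower in late against early stimulated, 323 lower in late stimulated against sensitive and 294 higher in refractory against late stimulated. Only genes listed in all 4 files gave 115 and 162, 24 and 81, 105 and 220, 115 and 42, and 132 and 175 in the 5 comparisons, with far fewer genes tested. Exon coverage gave 174 and 188 in late against early stimulated and 181 lower in refractory against late stimulated. On any strand these were 177, 186 and 180. With median-of-ratios scaling they were 190 and 166, and 261 and 227. Genes covered in both libraries gave 218 and 261 for early stimulated against sensitive, 58 and 128 for late against early stimulated, 217 higher for late stimulated against sensitive, 228 and 98 for refractory against late stimulated, and 249 and 297 for refractory against sensitive. With uncovered genes at the floor, 159 were higher in late against early stimulated, 343 and 978 in late stimulated against sensitive, 243 lower in refractory against late stimulated, and 414 and 886 in refractory against sensitive. These counts include genes covered in neither library, for which they compare the floors alone. They also include genes uncovered in 1 library and under its floor in the other, which have no measured direction. Leaving such genes out, as chosen last, gave 359 higher in early stimulated against sensitive, 80 higher in late against early stimulated, 291 higher in late stimulated against sensitive, 279 and 143 in refractory against late stimulated, and 366 higher in refractory against sensitive. Of 497 alternative list medians 430 moved by at most 0.5. Among lists past the outer percentiles, 2 changed sign, both for housekeeping genes when only the 4 members listed in all files were used, at 0.087 in late against early stimulated and -0.069 in refractory against late stimulated. Of 1128 alternative values of single genes 829 moved by at most 0.5, 286 moved further and 13 reversed. Those that moved further included 85 of 141 with a pseudocount of 0.1, 89 with one of 5, 73 at the floor and 38 under the genes' names. Single genes reversed where a gene had no transcript under its name in a library. In early stimulated against sensitive, values under the names were 3.90 for LHX9, 8.22 for ACTB and -6.79 for GAPDH, in late against early stimulated 3.22 for RLBP1, and in refractory against late stimulated -6.24 for ENO2, 5.13 for SCG3 and 7.42 for UCHL1. At the floor TCF21 came to 0.34, HOXD8 to 0.74, INHA to 1.48, TDRD6 to 2.26 and INHBA to -1.54 in early stimulated against sensitive, and RPL35 to -0.22 in late against early stimulated, so these genes have no measurable direction. The filters, the choice of highest transcript and the limit to genes listed in all files do not change the exon coverage of a single gene and gave no value for it.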

Other observations

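All tests in this part were chosen after the data were examined. Several lists fixed in advance had too few named members for a median. MSMO1, an enzyme of cholesterol synthesis, was at 44.0, 52.3, 85.3 and 68.8 FPKM in the libraries labelled sensitive, early stimulated, late stimulated and refractory. In the cell-cycle list CCND2 was at 47.2, 0, 9.87 and 0 FPKM and CCND1 at 0, 2.63, 0 and 3.72. Only late stimulated held a transcript under CCND2's name, so its direction there against sensitive reverses under the name. The apoptosis list held BCL2L1 at 20.1, 13.2, 13.3 and 15.4 FPKM and ENDOG at 11.3, 0, 3.35 and 8.66. ANGPT2, the endothelial list's only named gene, was at 44.2, 21.4, 17.4 and 20.6 FPKM. BMP4 of the Sertoli list was covered in refractory alone, at 0.28 FPKM. The lists of extracellular matrix, peritubular and smooth muscle, erythroid blood, immune, skeletal muscle, DNA and histone modification, and hypothalamic and pineal genes had 0 named members.

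The abundant named genes of the 4 libraries also differed. EEF1B2, a translation elongation factor, was the highest named gene in sensitive at 3378 FPKM and stood at 672, 550 and 975 FPKM in the others. GNB1, a G-protein beta subunit, stood at 1049, 958 and 871 FPKM in early stimulated, late stimulated and refractory against 350 in sensitive. CALB2, listed at 0 in sensitive, ranked 29, 53 and 38 of 1509 genes with a symbol in the others, while FABP4 ranked 18 in sensitive.

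Loci of all transcripts, named or not, were merged over the 4 files by exon overlap, which gave 21055 loci. Across loci covered in both libraries of a pair, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was 0.62, 0.60 and 0.58 for sensitive with early stimulated, late stimulated and refractory. It was 0.90 for early with late stimulated, 0.91 for early stimulated with refractory and 0.85 for late stimulated with refractory. Of 1714 loci at 62.3 FPKM or more in the last 3 libraries, 371 (21.6%) were listed at 0 in sensitive, although this level is 3 times the floor there. Of 2540 loci that high in sensitive, 237 (9.33%) were at 0 in all of the others.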
